A study of Homo sapiens with 6 samples.

How the data were processed

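Gene expression was measured in 6 samples of THP1, a monocytic acute myeloid leukaemia cell line, on Affymetrix Human Genome U133 Plus 2.0 arrays, 1 array per sample. The labels place 3 samples in an untreated group and 3 in a group cultured on plates coated with Dll4-Fc, the Notch ligand Delta-like 4 fused to an antibody Fc part. RNA was taken after 48 hours, per the labels' protocols. The treatment protocol names the control as vehicle, and the sample labels call it untreated; the protocol gives the coating as 30 nM and the sample labels give 60 nM, so the dose is left open here. The labels name no well coated with Fc alone. Total RNA, 5 ng per sample, was amplified to cDNA with the NuGEN Ovation system and labelled with biotin, per the labels' protocols. The labels do not say whether the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

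The deposited table holds 1 intensity per probe set and array, on a linear scale, for 54675 probe sets; the authors made it with RMA, a method that corrects background, normalizes by quantiles and summarizes probes, per the submitters' processing notes. Its version is not given in the sources used here. The median intensity per array lay between 50.6 and 52.7, the lowest value was 5.87 and the highest 28188, so nothing was filtered or floored and every value had a logarithm. RMA shrinks the differences of dim probe sets, and quantile normalization gives all arrays nearly the same distribution, so a change in total RNA per cell is not visible. The number of arrays limits the precision: the median standard error of a difference was 0.075 on the log2 scale.

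Here the intensities were log2 transformed. Genes were named from the platform annotation: 41097 probe sets had exactly 1 gene symbol, 1801 had several and 11777 were not listed there. Entrez numbers of 41043 of the probe sets with 1 symbol matched a current gene table (assembly GRCh38.p14, used for names only) and 54 did not; 0 symbols changed. Each of 19775 genes was represented by the probe set with the highest mean over the 6 arrays, which mattered for the 10523 genes with several probe sets. For 21 of the genes that passed the test, other probe sets passed in the opposite direction. The Dll4-Fc and untreated groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, 2-sided, 4 residual degrees of freedom) and p-values were adjusted by the Benjamini-Hochberg method over all genes, with 0.05 as the threshold. Differences are Dll4-Fc minus untreated on the log2 scale, ± is the standard error of that difference with n = 3 arrays per group, and folds are powers of 2 of it.

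The following choices were made before the data were examined: the test, the threshold, 27 gene lists with 665 entries between them (600 measured), of which 4 were primary, the alternatives, and the rule for named genes. Named are the 12 genes with the largest rise and the 12 with the largest fall among genes that passed with no overlap between the groups, up to 6 passing members of each primary list, up to 3 of each other list, and 14 further genes fixed by name: HES1, HES4, HEY1, NRARP, DTX1, NOTCH1, NOTCH2, DLL4, CD14, ITGAM, CSF1R, MYC, GAPDH and ACTB. Members named only to spell out a count of 5 or fewer, and genes named first in the closing observations, were chosen after their values were seen. Lists were tested with camera from limma at a preset correlation of 0.01, 2-sided and adjusted over the 27 lists, which compares a list with all other genes. Camera with an estimated correlation and fry, a test of whether a list's genes move on balance one way without comparing them with other genes, were alternatives. For each list the members passing were also counted with p-values adjusted over the list alone. Medians were set beside 10000 random lists of the same size matched on mean expression.

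The procedure was tested on simulated data with the 19775 genes and the spread of these arrays. Of 50 planted changes each, it recovered 4% at a log2 difference of 0.25, 52% at 0.5, 92% at 1 and 100% at 2, with 8 false calls among 132. A list shifted by 0.2 was found, and 0 of 26 unshifted lists were called. The simulated genes varied independently, while the estimated correlation in the data was 0.18 for the S phase and mitosis list and 0.72 for the interferon-stimulated list. The 0 of 26 therefore does not measure false list calls where the genes of a list vary together. Few genes were changed in the simulation, so its recovery rates need not carry over to data where many change. Signal ratios of 3' to 5' probe sets and the bacterial hybridization controls were compared by exact permutation tests. The alternatives were: the replicate number as a block, the mean of all probe sets of a gene, leaving out probe sets shared between transcripts, leaving out dim genes, cyclic loess or median centring between arrays, a variance prior with trend and robust fitting, array weights, an adjusted p under 0.1, all probe sets tested one by one, and leaving out each array in turn. No genome coordinates are given, because the table names no build. Plots were drawn with matplotlib 3.10.9.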

Results

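THP1, a monocytic acute myeloid leukaemia cell line, was cultured for 48 hours on plates coated with Dll4-Fc, the extracellular part of the Notch ligand Delta-like 4 joined to an antibody Fc part, or without it. Expression was measured on 6 arrays, 3 per group. The series title places the comparison in a study of how activating the Notch pathway affects the homeostasis and differentiation of acute myeloid leukaemia cells. Arrays of the same group correlated at r = 0.997 to 0.999 across genes and arrays of different groups at r = 0.981 to 0.985. The SD of the log2 difference between 2 arrays was 0.139 to 0.21 within a group and 0.467 to 0.514 between groups. The first principal component held 85.4% of the variance and separated the groups, and the next, with 6.14%, set untreated replicate 3 apart. The 3' minus 5' log2 signal of ACTB was 0.72 ± 0.05 (SD, n = 3) in untreated and 0.67 ± 0.03 in Dll4-Fc arrays, with an exact permutation p of 0.2. That of GAPDH was 0.38 and 0.39, with an exact permutation p of 0.9, and 3 arrays against 3 cannot give a p below 0.1. The gene-level signal of GAPDH, a glycolytic enzyme used as a reference gene, differed by 0.02 ± 0.05 and did not pass the test. That of ACTB, cytoskeletal actin, differed by 0.14 ± 0.05 (adjusted p = 0.0807), and it passed as higher without dim genes (0.0314), with array weights (0.0397) and with a trended robust prior (6.51e-05).

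In THP1 cells on Dll4-Fc, the signals of many macrophage, lipid-handling and interferon-response genes were higher, and those of the stem cell factor receptor gene KIT and of several granule protein genes were lower. The steepest rise was that of FABP4, a lipid-binding protein of adipocytes and macrophages, from a log2 signal of 5.32 ± 0.33 to 13.62 ± 0.05 (SD, n = 3), a difference of 8.29 ± 0.15 or 313.5-fold. It was followed by TDO2, which starts tryptophan breakdown (7.52 ± 0.14, 183.2-fold), SPP1, the secreted adhesion protein osteopontin (7.24 ± 0.14, 150.7-fold), and RGS1, a brake on G protein signalling (7.14 ± 0.26, 141.5-fold). The other 8 genes among the 12 largest rises were the interferon-stimulated IFI44L (6.68 ± 0.17) and IFIT1 (5.94 ± 0.28), the survival gene BCL2A1 (6.50 ± 0.11, 90.8-fold), the protease inhibitor A2M (6.48 ± 0.24), TRIM22 (6.37 ± 0.09), the protease ADAMDEC1 (6.11 ± 0.14), the NADPH oxidase subunit CYBB (6.03 ± 0.14, 65.6-fold) and the RNA-binding ZFP36L1 (5.97 ± 0.11). All 12 had an adjusted p of 7.83e-06 or less and no overlap between the groups. Most of the 12 started below the median probe set signal of 5.70, so their folds are uncertain in size. Other probe sets did not all pass for TDO2 and A2M (1 of 2 rose), RGS1 (2 of 3), CYBB and ZFP36L1 (2 of 4 each), and ZFP36L1 gave 0.18 (adjusted p = 0.192) without probe sets shared between transcripts.

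Falls were smaller. TBC1D30, a GTPase-activating protein of the TBC family, fell by 2.88 ± 0.36 (7.34-fold, adjusted p = 0.00111) and CNR1, a cannabinoid receptor, by 2.37 ± 0.14 on the log2 scale (5.18-fold, adjusted p = 2.5e-05). The muscle-associated STYXL2 fell by 2.15 ± 0.10, KIT by 2.03 ± 0.09 (4.09-fold, adjusted p = 4.42e-06) and SOCS2, a cytokine signalling inhibitor, by 2.02 ± 0.13. The long noncoding RNAs MIR1915HG and BALR6 differed by -1.96 ± 0.11 and -1.84 ± 0.20, and SYNPO2, an actin-binding protein, by -1.91 ± 0.15. MSRB3, a methionine sulfoxide reductase, differed by -1.77 ± 0.08, the collagen gene COL4A5 by -1.76 ± 0.15, the haematopoietic membrane protein gene MS4A3 by -1.71 ± 0.05 and the coagulation factor XIII subunit F13A1 by -1.70 ± 0.18. All 12 passed without overlap between the groups. Other probe sets did not all pass for TBC1D30 and SOCS2 (2 of 3 fell), CNR1 (2 of 4), SYNPO2 (5 of 7) and COL4A5 (1 of 2), and COL4A5 gave -0.15 (adjusted p = 0.216) without shared probe sets.

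Of 19775 genes, 5262 (26.6%) passed limma's test at an adjusted p under 0.05, 2298 higher and 2964 lower with Dll4-Fc. At least 2-fold, 515 genes were higher and 119 lower, and 47 were at least 16-fold higher against 5 at least 4-fold lower. The smallest difference that passed was 0.16 and the median over all genes was -0.01. The groups did not overlap for 8235 genes (41.6%), where chance gives 10%. The count of lower genes was 1854 without Dll4-Fc replicate 1 and 1959 without untreated replicate 2, and cyclic loess turned the split from 43.7% higher to 53.7% (2859 higher, 2466 lower). With the mean of all probe sets of a gene, 61 genes in place of 119 were at least 2-fold lower.

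Among Notch target genes, HES1, the main transcriptional repressor downstream of Notch, rose 7.65-fold (2.93 ± 0.20, adjusted p = 4.85e-05), from a log2 signal of 5.02 ± 0.42 to 7.95 ± 0.17 (SD, n = 3), and its relative HES4 rose 2.77-fold (1.47 ± 0.18, adjusted p = 0.000989). BCL6, a transcriptional repressor, rose 6.02-fold (2.59 ± 0.08) and CDKN1A, the cyclin-dependent kinase inhibitor p21, 3.49-fold (1.80 ± 0.06). Smaller rises included those of the ligand gene JAG1 (0.86 ± 0.19) and the receptor gene NOTCH1 (0.29 ± 0.06, adjusted p = 0.00961). In the opposite direction HEYL, a repressor related to HES1, fell by 0.65 ± 0.08 and MYC, a growth-promoting transcription factor, by 0.53 ± 0.05 (adjusted p = 0.000317). HEY1 differed by 0.09 ± 0.07 (adjusted p = 0.428), the Notch feedback gene NRARP by -0.14 ± 0.06 (0.122) and DTX1, which encodes a ubiquitin ligase, by -0.11 ± 0.11 (0.553), none past the threshold. Of the 21 measured members 8 rose and 2 fell, 10 and 2 adjusted over the list alone, with a median of 0.16 (0.09 with the mean of probe sets, 0.11 without shared probe sets and 0.50 without dim genes). Camera gave adjusted p = 0.00464, and adjusted p = 0.221 with an estimated correlation. JAG1 did not pass without Dll4-Fc replicate 1 (adjusted p = 0.0558), when 7 members rose. For HES1, 2 of 3 probe sets rose, by 3.50 and 2.93, and the only one not shared between transcripts gave 0.00 (adjusted p = 0.988). That probe set lay at 3.78 in untreated cells, below the median probe set signal of 5.70, so it cannot decide whether HES1 rose. The only HES4 probe set is also shared between transcripts and lay at 5.60 in untreated cells, below that median. The rises of HES1 and HES4 therefore rest on shared probe sets. Without shared probe sets 4 of 14 members rose and 0 fell, and HES4 was not measured.

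**Figure D1:**
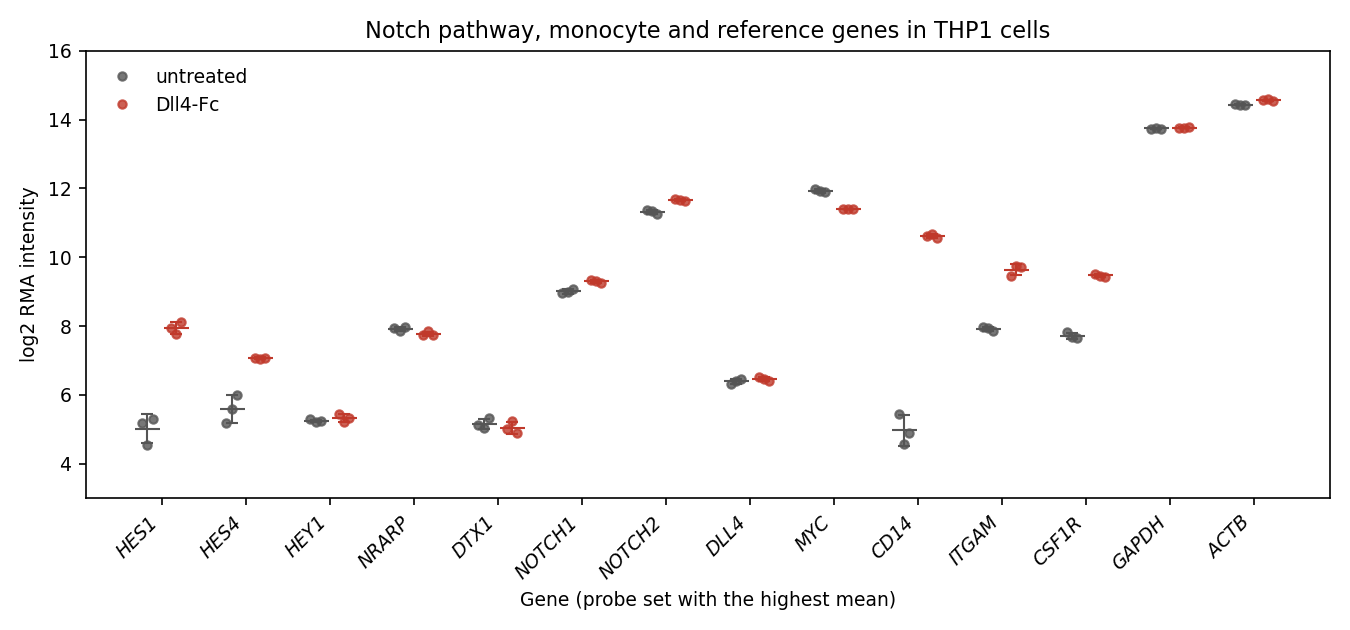
Log2 RMA intensity (vertical axis) of 14 genes fixed in advance, with 1 point per array, grey for untreated and red for Dll4-Fc, a horizontal bar at the mean and error bars of 1 SD (n = 3). HES1, HES4, CD14, ITGAM and CSF1R lie higher with Dll4-Fc, MYC lies lower (-0.53), and HEY1 (0.09) and GAPDH (0.02) overlap between the groups.

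Genes of the Notch machinery itself, 30 measured, did not move as a list (7 rose, 4 fell, 8 and 4 adjusted over the list alone; camera adjusted p = 0.529, and 0.638 with an estimated correlation). Of 22 measured without shared probe sets 3 rose and 2 fell, and 7 of the 30 fell with array weights and 1 with the mean of probe sets. MAML2, a coactivator of the Notch transcription complex, rose 14.5-fold (3.86 ± 0.15), PSEN2, a subunit of the Notch-cleaving gamma-secretase, rose by 0.78 ± 0.08 and the receptor gene NOTCH2 by 0.33 ± 0.06 (adjusted p = 0.00418). The 4 that fell were JAG2 (-0.62), MFNG (-0.32), APH1B (-0.31) and SPEN (-0.27); without untreated replicate 1, untreated replicate 2 and Dll4-Fc replicate 2 the number was 2, 1 and 1. DLL4, the gene of the ligand on the plate, differed by 0.07 ± 0.06 (adjusted p = 0.465). The median of this list was -0.03 and its mean 0.15.

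Most monocyte and macrophage differentiation genes rose. CD14, the monocyte coreceptor for lipopolysaccharide, rose 49.9-fold (5.64 ± 0.20, adjusted p = 1.81e-06), from 4.98 ± 0.45 to 10.62 ± 0.06 on the log2 scale (SD, n = 3). C1QC, a chain of the complement component C1q, rose 35.2-fold (5.14 ± 0.25), the proteoglycan gene VCAN 31.7-fold (4.98 ± 0.09), MERTK, a receptor for apoptotic cells, 24.2-fold (4.60 ± 0.15), the transcription factor gene MAF 20.5-fold (4.36 ± 0.07) and GPNMB, a glycoprotein of macrophage lysosomes, 13.9-fold (3.80 ± 0.07). CSF1R, the receptor for macrophage colony-stimulating factor, rose 3.37-fold (1.75 ± 0.06) and the integrin gene ITGAM (CD11b) 3.27-fold (1.71 ± 0.09). Of the 43 measured members 32 rose, 27 of them at least 2-fold, and 1 fell, the myeloid transcription factor gene CEBPA (-0.21), which did not pass when any array other than untreated replicate 3 was left out; adjusted over the list alone 33 rose and 3 fell. The number that fell was 4 with a trended robust prior and 3 with array weights or without dim genes. The median was 1.52, and 0.79 without shared probe sets. Camera gave adjusted p = 7.62e-23, and adjusted p = 0.073 with an estimated correlation. Without shared probe sets ITGAM gave -0.12 (adjusted p = 0.554) and MERTK 0.13 (0.212), so their rises rest on probe sets shared between transcripts.

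Many S phase and mitosis genes fell by small amounts, none of them 2-fold. The largest falls were those of CENPF, a kinetochore protein (-0.39 ± 0.05), the replicative helicase subunits MCM2 (-0.38 ± 0.05) and MCM4 (-0.35 ± 0.06), the topoisomerase gene TOP2A (-0.37 ± 0.06), the spindle factor gene TPX2 (-0.37 ± 0.07) and cyclin B2, CCNB2 (-0.36 ± 0.06). All 42 listed genes were measured, and 0 rose and 24 fell, 1 and 29 adjusted over the list alone. The median was -0.22, against -0.12 to 0.04 for the central 95% of random lists. Camera gave adjusted p = 1.1e-07, and adjusted p = 0.213 with an estimated correlation. The number that fell was 15 without Dll4-Fc replicate 1 and 13 of 33 without shared probe sets, where CENPF gave -0.13 (adjusted p = 0.365); CCNB2 gave -0.10 (0.203) as the mean of its probe sets. Inhibitors of the cell cycle went both ways: of 18 measured, 5 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.456, and 0.693 with an estimated correlation). The largest rises were those of CDKN1A, the antiproliferative BTG1 (1.07 ± 0.06, 2.09-fold) and the stress-induced SESN2 (0.80 ± 0.06). The 5 that fell were CDKN2D (-0.52), CCNG2 (-0.47), CDKN1B (-0.44), RBL2 (-0.28) and CCNG1 (-0.23), and their number was 3 without untreated replicate 2, Dll4-Fc replicate 1 or Dll4-Fc replicate 2. Of 14 measured without shared probe sets 3 rose and 2 fell. The median of that list was -0.04 and its mean 0.14.

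Genes of the apoptotic machinery changed in both directions. BIK, a killer of the BCL2 family, fell by 1.19 ± 0.06 (2.29-fold, adjusted p = 1.5e-05), while TNFSF10, the death ligand TRAIL, rose by 1.08 ± 0.17 (2.11-fold) and its receptor gene TNFRSF10B by 0.54 ± 0.05. BAK1, which permeabilizes mitochondria, rose by 0.57 ± 0.07 and BID, which activates it, by 0.40 ± 0.06. CASP6, an executioner caspase, fell by 0.40 ± 0.09 (adjusted p = 0.0183). Of 27 pro-apoptotic genes 6 rose and 5 fell, 7 and 5 adjusted over the list alone, with a median of -0.01 and a mean of 0.03. Camera gave adjusted p = 0.574, and 0.72 with an estimated correlation. Without untreated replicate 1, untreated replicate 2 and Dll4-Fc replicate 1, CASP6 did not pass (adjusted p = 0.0565, 0.0649 and 0.0566) and the number that fell was 3, 2 and 2. Among 8 anti-apoptotic genes 3 rose and 1 fell, also adjusted over the list alone: BCL2A1 rose 90.8-fold, XIAP by 0.36 ± 0.06 and MCL1 by 0.23, and BCL2 itself fell by 1.11 ± 0.06 (2.16-fold). The list did not pass (adjusted p = 0.574, and 0.687 with an estimated correlation), with a median of -0.02 and a mean of 0.71.

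All 31 measured interferon-stimulated genes rose at least 2-fold, by 1.14 up to 6.68 ± 0.17 for IFI44L (102.9-fold), with IFIT1, which binds viral RNA, at 61.3-fold (5.94 ± 0.28) and IFI44 at 57-fold (5.83 ± 0.13). The median was 3.22, the same 31 passed adjusted over the list alone, and camera gave adjusted p = 1.72e-37, and adjusted p = 0.155 with an estimated correlation. Of 27 NF-kB target and inflammatory cytokine genes 13 rose and 0 fell, 14 and 1 adjusted over the list alone (median 0.32, adjusted p = 6.36e-07, and 0.206 with an estimated correlation). The chemokine gene CXCL10 rose 15.7-fold (3.98 ± 0.17), IL1B 6.47-fold (2.69 ± 0.15) and the interleukin 1 antagonist IL1RN 6.92-fold (2.79 ± 0.11), although IL1RN gave -0.032 (adjusted p = 0.92) without shared probe sets. Without those probe sets 8 of 21 members rose and the median was 0.11. It was 0.59 without dim genes, and 1 member fell without Dll4-Fc replicate 3. Of 24 immediate early genes 11 rose and 1 fell, 14 and 1 adjusted over the list alone (median 0.33, or 0.21 with the mean of probe sets, adjusted p = 1.85e-06, and 0.155 with an estimated correlation), led by the stress-induced ATF3 (3.57 ± 0.13) and the phosphatase genes DUSP1 (2.34 ± 0.14) and DUSP6 (2.03 ± 0.06), while their relative DUSP5 fell (-0.22), a call lost without untreated replicate 1 or any of the Dll4-Fc arrays. Of 26 integrin and adhesion genes 13 rose and 3 fell, 14 and 3 adjusted over the list alone (median 0.24, adjusted p = 4e-06, and 0.208 with an estimated correlation), with SPP1, the tetraspanin CD9 (3.23 ± 0.11) and ITGA6 (2.86 ± 0.10) at the top. SELPLG (-0.93), ITGA2 (-0.64) and ICAM3 (-0.29) fell, 1 of them when untreated replicate 1, untreated replicate 2, Dll4-Fc replicate 1 or Dll4-Fc replicate 2 was left out.

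More genes of the antigen presentation list rose than fell, and more granulocyte genes fell than rose. Of 25 MHC class II and dendritic cell genes 16 rose, 11 of them at least 2-fold, and 1 fell, HLA-DQB1 (-0.40), the same counts adjusted over the list alone (median 0.52, adjusted p = 1.12e-08, and 0.155 with an estimated correlation). The median was 0.94 without untreated replicate 1 or 2, 0.88 without untreated replicate 3, 0.92 without shared probe sets and 1.07 without dim genes. The lipid-presenting CD1C rose 12.7-fold (3.67 ± 0.09), the lectin CD209 5.37-fold (2.43 ± 0.09) and CD1B 4.54-fold (2.18 ± 0.10). Of 19 granulocyte genes 9 fell and 2 rose, also adjusted over the list alone (median -0.11, adjusted p = 0.012, and 0.213 with an estimated correlation). Its median was -0.26 without Dll4-Fc replicate 2, -0.45 without shared probe sets and -0.80 without dim genes, and 8 of the 19 did not pass. The azurophil granule proteases CTSG and PRTN3 fell 2.83-fold and 2.47-fold (log2 standard errors 0.06 and 0.07), while the matrix proteases MMP9 and MMP8 rose by 2.63 ± 0.17 and 0.64. Of 17 measured genes of the leukaemia stem cell and HOX list, none a HOXA gene, 8 fell and 2 rose, FLT3 (0.28) and ID2 (0.49), also adjusted over the list alone. KIT fell by 2.03 ± 0.09, the cell cycle kinase gene CDK6 by 0.66 ± 0.06 and MYC by 0.53 ± 0.05. This list had a median of -0.10 and adjusted p = 0.0454, and 0.312 with an estimated correlation; it did not pass without untreated replicate 1 (0.0505), untreated replicate 2 (0.0616) or Dll4-Fc replicate 1 (0.0539), with the mean of probe sets (0.104), without shared probe sets (0.0556) or without dim genes (0.0922). Its median was -0.15 without untreated replicate 2 or 3, -0.16 without Dll4-Fc replicate 1 or 2 and -0.29 without dim genes, and 1 member rose without Dll4-Fc replicate 2.

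Markers of other cell types did not move as lists. Of 18 erythroid and megakaryocyte genes TFRC (0.38 ± 0.05) and GATA2 (0.28 ± 0.06) rose and GP9 (-0.25 ± 0.06) fell, with an adjusted p of 0.456, and 0.72 with an estimated correlation. Of 19 T lymphoid genes CD1A (1.25 ± 0.15) rose and BCL11B (-0.999 ± 0.10) fell (adjusted p = 0.574, and 0.72 with an estimated correlation). Of 13 B lymphoid genes PAX5 (0.60 ± 0.10) rose and BANK1 (-0.74 ± 0.11) fell (adjusted p = 0.79, and 0.852 with an estimated correlation), and the median was 0.0031 with a mean of -0.0046. Of 17 fibroblast, endothelial and epithelial genes PECAM1 (0.55 ± 0.06), which monocytes also express, rose and ACTA2 (-0.33 ± 0.09) fell (adjusted p = 0.789, and 0.852 with an estimated correlation), and the median was -0.04 with a mean of 0.01. Adjusted over the list alone the counts were the same, except that ACTA2 did not pass. Among T lymphoid genes 2 rose without untreated replicate 2, untreated replicate 3 or Dll4-Fc replicate 3 and 2 fell without untreated replicate 3. Among B lymphoid genes 2 rose without untreated replicate 1 or Dll4-Fc replicate 3 and 2 fell without Dll4-Fc replicate 2. GP9 did not pass when any array but untreated replicate 2 or 3 was left out (adjusted p = 0.0508 to 0.0751), nor ACTA2 without untreated replicate 1 or 2 or Dll4-Fc replicate 1 or 2 (0.0606 to 0.0897), nor GATA2 without untreated replicate 1 (0.0514). With the mean of probe sets GATA2 gave 0.14 (0.186) and ACTA2 -0.08 (0.381). With cyclic loess GP9 gave 0.0719 and ACTA2 0.0532 as adjusted p.

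Of 26 lysosome genes 19 rose and 0 fell, 20 and 0 adjusted over the list alone (median 0.68, adjusted p = 1.19e-13, and 0.155 with an estimated correlation), with the cathepsin genes CTSL (2.40 ± 0.07, 5.29-fold), CTSH (1.84 ± 0.05) and CTSD (1.57 ± 0.12) at the top. Of 20 measured without shared probe sets 12 rose. Of 15 cholesterol efflux and lipid storage genes 10 rose and 2 fell, 11 and 2 adjusted over the list alone (median 1.30, adjusted p = 1.31e-07, and 0.0959 with an estimated correlation); after FABP4 came the lipoprotein gene APOE (8.35-fold, 3.06 ± 0.11) and the scavenger receptor gene CD36 (6.59-fold, 2.72 ± 0.08), and MYLIP (-0.59) and PLTP (-0.57) fell. Without shared probe sets 5 of 9 rose and 1 fell with a median of 0.48, and the median was 0.76 with the mean of probe sets. Of 17 cholesterol and fatty acid synthesis genes 9 rose and 1 fell, 10 and 3 adjusted over the list alone (median 0.26, adjusted p = 0.00206, and 0.312 with an estimated correlation), led by MSMO1 (0.72 ± 0.06), HMGCS1 (0.69 ± 0.05) and DHCR7 (0.63 ± 0.12). The median was 0.13 with the mean of probe sets and 0.16 without shared probe sets, where 5 of 13 rose, and 4 fell with array weights. The 1 that fell, SREBF1 (-0.19), did not pass without untreated replicate 1 or 2 or Dll4-Fc replicate 1 or 2. Of 20 unfolded protein and amino acid stress genes 16 rose and 1 fell, 17 and 1 adjusted over the list alone (median 0.71, adjusted p = 3.01e-10, and 0.155 with an estimated correlation), with ATF3, HERPUD1 (1.01 ± 0.06) and the asparagine synthetase gene ASNS (0.99 ± 0.10) at the top. EDEM1 (-0.24) fell, but did not pass without untreated replicate 2 or Dll4-Fc replicate 1 or 2. HERPUD1 and ASNS gave 0.17 (adjusted p = 0.247) and 0.11 (0.523) without shared probe sets, where 10 of 15 members rose. Of 19 heat shock and oxidative stress genes 9 rose and 0 fell, also adjusted over the list alone (median 0.13, adjusted p = 0.000368, and 0.27 with an estimated correlation); HMOX1, the haem-degrading oxygenase, rose 30.8-fold (4.95 ± 0.14), GCLC 3.08-fold (1.62 ± 0.10) and NQO1 by 0.74 ± 0.06. Without shared probe sets 2 of 10 members of this list rose, with a median of 0.08, and it did not pass (0.0749). With cyclic loess the median was 0.20.

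Of 17 ribosome biogenesis genes 3 rose, NOP2 (0.36 ± 0.07), RRP12 (0.29 ± 0.07) and RRS1 (0.28 ± 0.05), and 1 fell, FBL (-0.21), which did not pass without untreated replicate 2 or Dll4-Fc replicate 1 or 2, with the same counts adjusted over the list alone (median 0.07, adjusted p = 0.0454, and 0.27 with an estimated correlation). That list did not pass without untreated replicate 2 (0.0651), untreated replicate 3 (0.0942), Dll4-Fc replicate 1 (0.0531) or Dll4-Fc replicate 3 (0.0883), nor with the mean of probe sets (0.146), without shared probe sets (0.0584), without dim genes (0.0522), after median centring (0.0784) or with array weights (0.0614). With cyclic loess 8 rose, the median was 0.10 and the list passed (0.0126), and 5 rose without dim genes or with a trended robust prior. Of 26 ribosomal protein genes 0 rose and 1 fell, RPL18 (-0.20 ± 0.05), 0 and 0 adjusted over the list alone (median -0.07, adjusted p = 0.0162, and 0.411 with an estimated correlation); the list gave 0.0504 without Dll4-Fc replicate 2 and 0.103 without shared probe sets. With a trended robust prior 17 of the 26 fell. The number was 4 with array weights or without dim genes, 3 with the mean of probe sets, 3 of 18 without shared probe sets and 2 without untreated replicate 3. Of 27 respiratory chain genes NDUFA9 (0.31 ± 0.08) and SDHD (0.27 ± 0.05) rose and NDUFS3 (-0.33 ± 0.05) fell, 1 and 1 adjusted over the list alone, and 5 fell with a trended robust prior (adjusted p = 0.634, and 0.852 with an estimated correlation). RPL18 did not pass without untreated replicate 1 or 2 or Dll4-Fc replicate 1 or 2 (0.0711 to 0.1), RRP12 without untreated replicate 2 or 3 or Dll4-Fc replicate 2 or 3 (0.0536 to 0.0843), and NDUFA9 without untreated replicate 2 or any of the Dll4-Fc arrays (0.0518 to 0.0921). With the mean of probe sets RPL18 gave -0.11 (0.231), RRP12 0.17 (0.0827) and SDHD 0.17 (0.06), and without shared probe sets RRP12 gave 0.06 (0.704). After median centring RPL18 (0.0514) and NDUFA9 (0.0552) did not pass. Of 25 hypoxia and glycolysis genes 9 rose and 4 fell, 10 and 4 adjusted over the list alone (median 0.10, adjusted p = 0.109, and 0.546 with an estimated correlation). The angiogenic factor gene VEGFA rose 3.06-fold (1.61 ± 0.17) and the hexokinase gene HK1 2.1-fold (1.07 ± 0.06), and the mitophagy receptor gene BNIP3 fell by 0.87 ± 0.06, as did PDK1 (-0.30), ALDOC (-0.26) and P4HA1 (-0.23). The number that fell was 1 without untreated replicate 2, untreated replicate 3 or Dll4-Fc replicate 1 and 2 without Dll4-Fc replicate 2. The median was -0.08 without shared probe sets, where 4 of 17 rose and 1 fell. This list passed with a trended robust prior (0.0333). Of all 27 lists 17 passed, 13 up and 4 down, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.073.

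**Figure D2:**
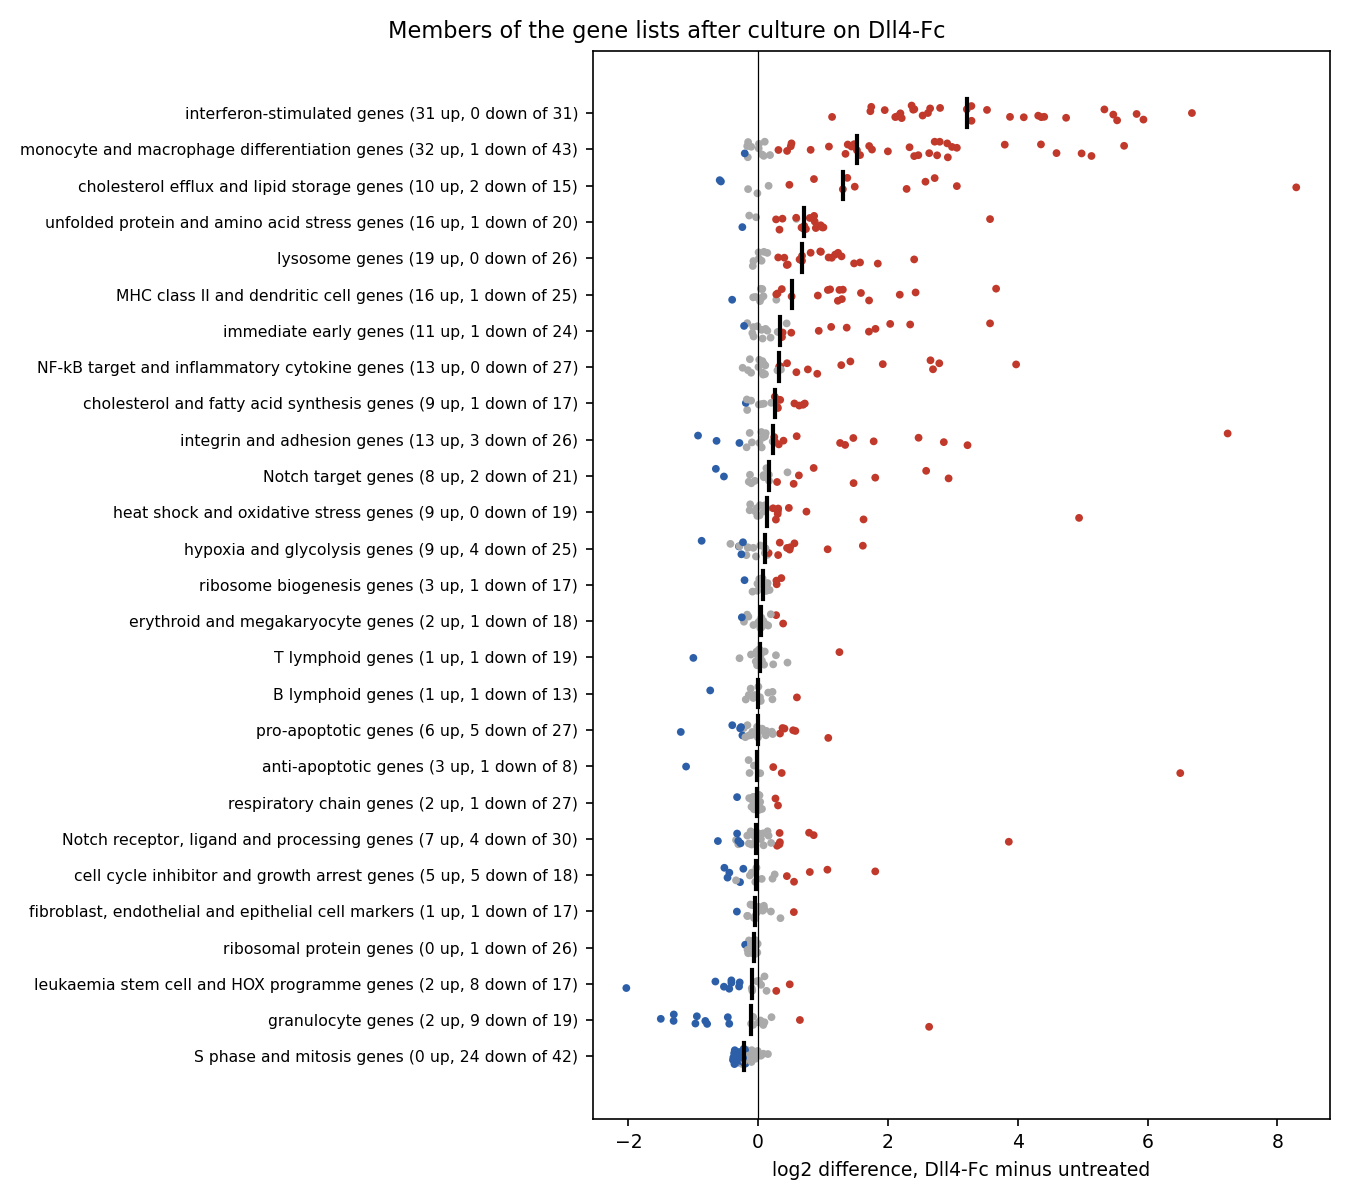
Log2 difference, Dll4-Fc minus untreated (horizontal axis), of each measured member of 27 gene lists, with red points for genes that rose, blue for genes that fell and grey for genes that did not pass, and a black bar at each list's median. The interferon-stimulated list has the highest median (3.22) and the S phase and mitosis list the lowest (-0.22).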

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

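No test in this part was chosen after its result was seen. Probe sets outside the gene-level comparison, with several gene symbols or none in the annotation, also carried differences: of 13522 of them, tested with limma and adjusted among themselves, 323 were higher with Dll4-Fc and 511 lower, 58 and 20 of them at least 2-fold, with a largest rise of 6.46 on the log2 scale. They stand out because they are signal that the comparison of named genes does not use, and they are left unnamed.

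Regrouping the 6 arrays into other sets of 3 and 3 gives 10 splits with the real one, too few for a share under 0.05. The real grouping called 5262 genes, and 634 at least 2-fold, and the highest count in any other split was 0 for both. Of the 10 splits 1 reached each real count. Every other split mixes Dll4-Fc and untreated arrays, so the group difference enters its residual spread and a low count follows from the design. The contrast with 0 therefore does not measure how likely the real counts are by chance.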

How the results depend on the processing

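No alternative in this part was chosen after the data were seen. The number of changed genes, 5262, ranged from 3641 to 5464 when 1 array was left out and from 3830 (17100 genes, without shared probe sets) to 6941 (array weights) under the other gene-level settings; genes lower, 2964, ranged from 1854 to 3186 when 1 array was left out and from 2061 (replicate block) to 4137 (array weights) under the others. Tested one by one, 9000 probe sets passed, 3941 higher and 5059 lower, a count of probe sets in place of genes. The mean of all probe sets per gene left 61 genes at least 2-fold lower in place of 119; the cause was not tested. Cyclic loess gave 53.7% higher in place of 43.7%. With the replicate number as a block 3890 genes passed (1829 higher, 2061 lower), 3811 of them among the 5262, all in the same direction, and all 634 genes that changed at least 2-fold still passed; the leukaemia stem cell (0.0504) and ribosome biogenesis (0.0686) lists did not. Same-numbered arrays did not deviate together (r from -0.21 to 0.01), against -0.04 to 0.22 for differently numbered arrays of the 2 groups. With 3 same-numbered pairs, whether the numbers mark a pairing stays open. With an estimated correlation the Notch target list gave adjusted p = 0.221, the monocyte and macrophage list 0.073 and the S phase and mitosis list 0.213, and 0 of 27 lists passed; fry passed 21. Under the other settings these lists kept their direction and passed, the Notch list at 0.000735 to 0.0142, and the pro-apoptotic list passed under none. Without shared probe sets IL1RN (-0.032, limma adjusted p = 0.92) and ITGAM (-0.12, 0.554) changed sign but did not pass. The probe sets left for these genes are dimmer than the chosen ones, so a change there is neither shown nor excluded. The cause was not tested. Fry added the anti-apoptotic (6.62e-05), cell cycle inhibitor (0.00242), Notch receptor, ligand and processing (0.00521) and hypoxia (0.0167) lists; unlike camera it does not compare a list with the other genes. Of 113 named genes, calls were lost by 5 with the block, 6 with the mean of probe sets, and 2 each with loess and centring. Without shared probe sets 8 lost their call beside IL1RN and ITGAM. There 75 others did not change in call and the rest of the 113 were not measured. Leaving out an array lost 1 to 6 calls, while ACTB gained a call under 3 settings. Medians near 0 of several lists that did not pass changed sign under some settings. Of the 12 largest rises, all but those of SPP1 (5.87) and CYBB (6.34) start below the median probe set signal of 5.70. Examples are FABP4 (5.32) and BCL2A1 (3.81). The rises of CD14 (4.98), C1QC (4.15), MERTK (4.27) and HES1 (5.02) start below it too. At such levels RMA values lie near background. Their folds are therefore uncertain in size, and so is the order of the largest rises.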

Other observations

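The test of markers of other cell types was chosen after the result was seen; the other tests of explanations were not, but the rule for reading the last of them, on HEY1, NRARP and DTX1, was made stricter after its result was seen. The genes of this paragraph and the next were chosen after their values were seen. Of the interferon genes 5 were looked at, and these did not pass limma's test while interferon-stimulated genes did: IFNB1 differed by 0.18 ± 0.11 (adjusted p = 0.283), IFNA1 by -0.05, IFNA2 by 0.02, IFNL1 by 0.04 and IFNG by 0.04 (adjusted p = 0.875), all from log2 signals of 3.13 to 5.46 in untreated cells. Of 6 genes looked at that interferon gamma is known to induce, CXCL10 (3.98), CXCL11 (1.45, adjusted p = 0.00388) and CXCL9 (0.41, adjusted p = 0.00927) passed, and IDO1 (-0.11), CIITA (0.03) and SOCS1 (0.26) did not. Of 6 innate sensing genes looked at, LY96, the partner of TLR4 in lipopolysaccharide recognition, rose by 5.62 ± 0.06 (49.3-fold) and TLR8, a receptor for single-stranded RNA, by 4.38 ± 0.09 (20.9-fold). TLR4 itself rose by 1.09, while TLR2 (0.01), TLR3 (0.09, where 1 of 3 probe sets rose) and TLR9 (0.07) did not pass.

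GNLY, a granule protein of cytotoxic lymphocytes, rose 39.4-fold (5.30 ± 0.12), but NKG7 (0.07), GZMB (0.03) and PRF1 (0.03), genes of the same cells, did not pass. CD52 rose 28.6-fold (4.84 ± 0.10), the aromatase gene CYP19A1 25.5-fold (4.67 ± 0.12) and the macrophage elastase gene MMP12 23-fold (4.52 ± 0.07). In the other direction the chemokine gene CCL23 (-1.55 ± 0.08), SERPINB10 (-1.55 ± 0.10) and the leukotriene synthase gene LTC4S (-1.53 ± 0.10) were lower, each with an adjusted p of 4.51e-05 or less.

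All 31 measured interferon-stimulated genes rose. Cells of another type in the treated wells were looked for through 67 markers of lymphoid, erythroid, megakaryocytic, fibroblast, endothelial and epithelial cells. Of these, 5 rose (7.46%), CD1A, TFRC, GATA2, PAX5 and PECAM1, and 4 fell, with a median of 0.02. Among all 19775 genes 2298 rose. CD3E (-0.04), MS4A1 (-0.19), COL1A1 (0.09) and HBB (-0.22) were among those that did not pass. In untreated cells 30 of the 67 lay above the array median, and 2 are in another list. The markers as a set did not rise. This test and its rule were chosen after the result was seen, so the count decides nothing by itself. An innate stimulus such as endotoxin carried on the protein coat may contribute and cannot be told apart from the ligand. Of 9 acute endotoxin-response genes 6 rose, between the 7 at 2-fold that it called for and the 0 set in advance as going against it. Only 3 of the 9 rose at least 2-fold, IL1B (2.69), CXCL8 (2.66) and CCL4 (1.92), while IL6 (-0.13), NFKBIA (0.02) and CCL20 (0.35) did not pass. RNA was taken after 48 hours, when an acute response may have passed, so even a count of 0 could not have excluded it. A response to Dll4 itself stays open and untested, since the labels name no well with Fc alone.

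S phase and mitosis genes fell by a median of 0.22 on the log2 scale, small enough that normalization could be thought to produce it. Against a shift of genes at that brightness, 0 of 10000 random lists matched on mean expression had a median as low. The genes of those lists were drawn independently, while the estimated correlation within this list was 0.18. The spread of the random lists may therefore be too narrow for genes that vary together. Camera with an estimated correlation did not pass (adjusted p = 0.213). Against untreated replicate 3, the array that stands apart, 24 members fell without it, as many as with it. What underlies the fall is left open; MKI67 (0.04) did not pass, and cell numbers are not analysed here.

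HEY1, NRARP and DTX1 did not pass while HES1 and HES4 rose. A probe set that misses the change may explain this and cannot be told apart from a response limited to some Notch targets. Whether the rises of HES1 and HES4 came through Notch at all was not tested. Low signal could hide a rise of HEY1 (5.24 in untreated cells) and DTX1 (5.16), which lay below the array median. The only NRARP probe set lay above it, at 7.92, so low signal does not explain NRARP. The 95% interval of NRARP was -0.284 to -0.006 in the gene-level test and -0.30 to 0.01 with all probe sets tested. NRARP thus leaned lower but did not pass limma's test (gene-level adjusted p = 0.122). Whether that probe set misses a rise for another reason was not tested. Of the other probe sets of the 3 genes 0 rose, but there is only 1, for HEY1, at 0.07 with a 95% interval of -0.09 to 0.23. That interval met the bound set in advance against this explanation, and by that rule alone the explanation would have been set aside. The stricter rule, added afterwards, asks for a further probe set above the array median for each gene: this probe set lies at 4.80 in untreated cells, below the array median, and NRARP and DTX1 have no other probe set. For HES1, 1 of 3 probe sets gave 0.00 where the other 2 rose, and it lay at 3.78 in untreated cells, also below the array median. HES4 has a single probe set, shared between transcripts, at 5.60 in untreated cells.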
